A study of Homo sapiens with 12 samples.

How the data were processed

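RNA was sequenced from the human gastric cancer cell lines AGS and MKN1, each untreated and treated with cantharidin sodium, in 4 groups of 3 libraries that the series' design text calls biological replicates. Dose and duration of treatment are not given in the sources used here. Per the labels' protocols, cells grew in RPMI-1640 medium with fetal bovine serum, total RNA was extracted with TRIzol, and libraries were made from fragmented mRNA with the NEBNext Ultra RNA kit. This kit does not mark the strand, and how strand was treated in counting is not given in the sources used here, so antisense genes are reported as uncertain. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.4 to the genome build hg38/GRCh38. The counting tool and the annotation release are not given in the sources used here.

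The deposited values are raw counts per gene, with 32269 Ensembl identifiers in 12 columns and no normalization by the authors. Symbols came from a table of current gene names, which matched 32069 identifiers. The 200 unmatched identifiers held at most 0.36% of the counts of a library. GENCODE release 29 gave a GRCh38 position for 32136 identifiers. Column totals lay between 28604966 and 51604215 counts, so that 3 counts, the floor used for values of 0, stood for 0.058 to 0.105 CPM in a library. Floors and intervals cover counting error only, because reads without molecular identifiers are not independent molecules.

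All counts were modelled together with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr over the 4 groups, which left 20280 genes, and libraries were scaled with TMM factors. Quasi-likelihood F tests compared treated with untreated cells in AGS and in MKN1, and a further contrast, MKN1 minus AGS, tested the difference between these effects. The fit had 8 residual and 4.91 prior degrees of freedom and a common biological coefficient of variation of 19.7%. P-values were adjusted by the Benjamini-Hochberg method over all tested genes with a threshold of 0.05, and numbers with an absolute log2 fold change of at least 1 were also taken. A higher or lower level below means treated against untreated. Levels are CPM as mean ± SD over the 3 libraries of a group, and log2 fold changes carry the standard error (SE) of the fit.

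Before the data were examined, the groups, contrasts, tests, thresholds, the rule for named genes and 32 gene lists were written down. The lists hold PP2A and related phosphatases, immediate early genes, ERK feedback genes, NF-kB target genes, p53 target genes, ATF4 and integrated stress response genes, endoplasmic reticulum chaperone genes, cytosolic heat shock genes, NRF2 target genes, DNA replication and G1/S genes, G2/M and mitosis genes, homologous recombination and Fanconi genes, replication-dependent histone genes, pro-apoptotic genes, anti-apoptotic genes, autophagy and lysosome genes, ribosome biogenesis genes, cytosolic ribosomal protein genes, mitochondrially encoded genes, nuclear oxidative phosphorylation genes, hypoxia and glycolysis genes, cholesterol biosynthesis genes, fatty acid synthesis genes, interferon-stimulated genes, YAP/TAZ target genes, Wnt target genes, mesenchymal and TGF-beta genes, epithelial junction genes, gastric epithelial genes, squamous epithelial genes, fibroblast, endothelial and blood cell marker genes, and matrix protease and invasion genes. Each list was tested with edgeR's camera at the preset correlation between genes of 0.01 and adjusted over the lists of a contrast. The camera test was repeated with a correlation estimated from the data. Members past the threshold were counted after adjustment over all genes and again over the list alone.

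Named genes followed a fixed rule. In each line these were the 6 largest increases and 6 largest decreases among genes with an ordinary symbol, an adjusted p below 0.05, a mean of at least 5 CPM in the line, and all 3 treated libraries on the same side of all 3 untreated libraries. To these came the 2 members of each list with the smallest adjusted p (1 where the list did not pass), and for the difference the 5 largest values in each direction by the same rule over 12 libraries. PPP2CA, PPP2CB, PPP1CA, PPP1CB and PPP1CC were given whatever their values. Some genes that the rule names are not reported here, and numbers of named calls include them. Further members of a list could be named by largest change among those past the threshold, with the same minimum. Genes that share exons with other genes were looked up in GENCODE release 29, over either strand. XIST and Y-linked genes were left out.

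Alternatives fixed beforehand were DESeq2 size factors, upper-quartile factors and library totals alone in the edgeR fit, the tests of DESeq2 1.42.0 and of limma 3.58.1 (voom), no filter on low counts, a filter of 5 CPM in 3 libraries, the replicate number as a block, each line fitted alone, each of the 12 libraries left out in turn, a test against a log2 fold change of 1 (glmTreat), an adjusted p below 0.01 for shared genes, and the list tests fry and camera with ranks. Alternatives added after the data had been seen were a restriction to genes of at least 1 CPM in the line or in both lines, the list test on each line fitted alone, and a fit in which each library's trend on transcript GC content and length was taken out. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

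The procedure was tested on simulated data with changed genes planted in the same design, with 19928 genes tested. Of genes changed 2-fold, 74.6% were recovered with the right sign in the simulated AGS groups, 64.2% in the simulated MKN1 groups and 36.9% for a difference of that size. Of genes changed 1.5-fold, the shares were 29.9%, 11.9% and 3.7%. False calls made up 5.7%, 6.6% and 5.8% of the calls. Simulated genes were independent and had the same spread in both lines, whereas real MKN1 replicates varied more than AGS replicates. These shares may therefore not hold for MKN1. A list changed only in the simulated AGS groups was called for AGS and the difference. It was not called for MKN1, where it had not been changed.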

Results

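The series measured mRNA in 12 libraries of 2 human gastric cancer lines, AGS and MKN1, grown with or without cantharidin sodium. Cantharidin sodium is a salt of the blister beetle toxin cantharidin, which is known to inhibit the serine/threonine phosphatases PP2A and PP1. Each line had 3 untreated and 3 treated libraries. Untreated AGS libraries held 51604215, 34890634 and 40052774 counts and treated AGS libraries 32772339, 39744350 and 35717586. Untreated MKN1 libraries held 30105404, 28655540 and 32124107 counts and treated MKN1 libraries 32057648, 28604966 and 38269048. Mitochondrially encoded genes took 4.42% to 9.65% of the counts.

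Within each line, the first principal component separated all treated AGS libraries from all untreated ones, whereas MKN1 untreated replicate 3 lay towards the treated side. Pearson correlations of log2 CPM between AGS replicates were 0.9876 to 0.9901. In MKN1, untreated replicates 1 and 2 correlated at 0.9853, while replicate 3 reached 0.9702 and 0.9722 with them, and treated replicates lay between 0.9771 and 0.9815. The median SD of log2 CPM between replicates was 0.10 and 0.09 in untreated and treated AGS cells and 0.20 and 0.21 in MKN1 cells. No library was a copy of another replicate of its group, since the lowest ratio of chi-square to degrees of freedom within groups was 10.4.

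**Figure D1:**
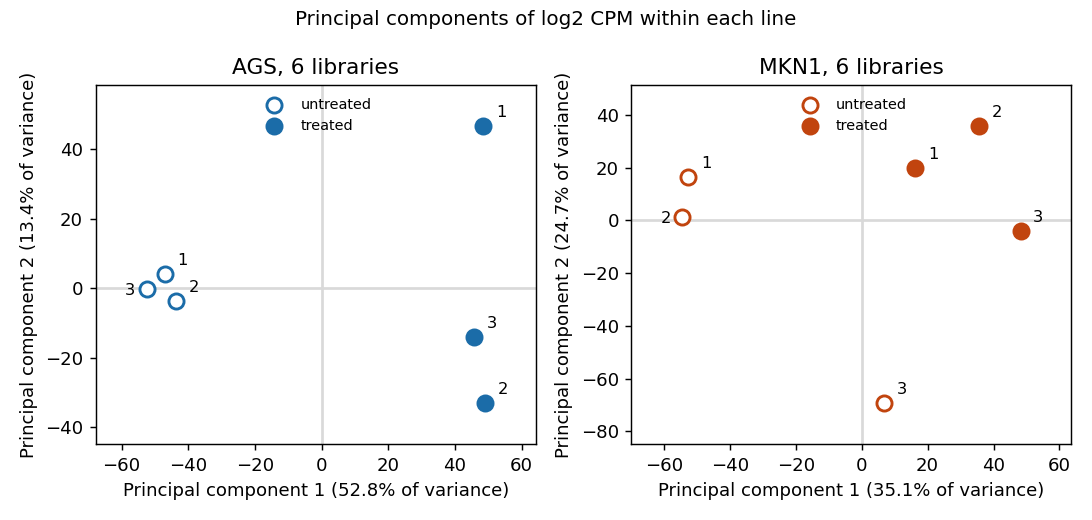
Principal components of log2 CPM within AGS and within MKN1, with 6 libraries each. Component 1 held 52.8% of the variance in AGS and 35.1% in MKN1, and numbers beside the points are replicates.

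The comparison in AGS asked which transcripts differ after cantharidin sodium. Cholesterol biosynthesis genes fell in treated AGS cells (n = 3 per group throughout). DHCR7 (ENSG00000172893, chromosome 11, 71428193 to 71452868 in GRCh38), which encodes the last enzyme of cholesterol synthesis, went from 118 ± 7.0 CPM to 37.9 ± 3.72 CPM, a log2 fold change of −1.64 (SE 0.14, adjusted p = 5.13e-05). INSIG1, a sterol-regulated anchor of the SREBP transcription factors, changed by −1.65 (SE 0.21, adjusted p = 0.000513), and IDI1, an enzyme of isoprenoid synthesis, by −1.55 (SE 0.20, adjusted p = 0.000513). ACAT2, whose enzyme makes the acetoacetyl-CoA that enters the pathway, fell by 1.33 (SE 0.14, adjusted p = 0.000144), although 52.3% of its exon bases overlap genes on the other strand. FASN, the fatty acid synthase gene, fell by 1.15 (SE 0.14, adjusted p = 0.00045). Of 25 cholesterol genes, 19 were lower and 0 higher after adjustment over all genes, and 21 were lower and 1 higher when adjusted over the list alone. Their median log2 fold change was −0.78, with library medians of −0.74, −0.87 and −0.75 in the treated cells. The camera test gave adjusted p = 1.12e-18, and adjusted p = 0.147 with an estimated correlation.

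Chaperone genes also fell in AGS. CALR, which encodes the calcium-binding lectin calreticulin, went from 1385 ± 53.8 CPM to 665.9 ± 49.3 CPM (log2 fold change −1.06, SE 0.14, adjusted p = 0.000513). MANF, a secreted protein of the endoplasmic reticulum stress response, fell by 1.13 (SE 0.15, adjusted p = 0.000513), and FKBP4, a cochaperone of HSP90, fell by 0.81 (SE 0.14, adjusted p = 0.00274). HSPB1, a small heat shock protein gene, changed by −0.77. Of 19 cytosolic heat shock genes, 12 were lower over all genes and 14 when adjusted over the list alone, with a median of −0.55 (adjusted p = 8.18e-06). This was adjusted p = 0.371 with an estimated correlation. Of 22 endoplasmic reticulum chaperone genes, 8 were lower and 2 higher over all genes, and 10 lower and 2 higher over the list alone (median −0.22, adjusted p = 0.000367). Their adjusted p = 0.371 with an estimated correlation.

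Genes driven by the transcriptional coactivators YAP and TAZ rose in AGS. CCN2 (ENSG00000118523, chromosome 6, 131948176 to 131951373), a matricellular growth factor gene, went from 30.0 ± 13.6 CPM to 116 ± 60.9 CPM (log2 fold change 1.95, SE 0.44, adjusted p = 0.00888). CRIM1, a transmembrane regulator of BMP signals, rose by 1.15 (SE 0.13, adjusted p = 0.000295), and DLC1, a tumour suppressor gene, rose by 0.67 (SE 0.13, adjusted p = 0.00428). Of 24 YAP/TAZ target genes, 10 were higher and 1 lower under both adjustments (median 0.38, adjusted p = 2.97e-05). The list gave adjusted p = 0.147 with an estimated correlation. ITGA3, the integrin alpha 3 gene, rose by 0.94 (SE 0.16, adjusted p = 0.00262). Of 19 matrix protease and invasion genes, 5 were higher and 0 lower over all genes and 6 were higher over the list alone (median 0.37, adjusted p = 0.0083). That list had adjusted p = 0.371 with an estimated correlation, adjusted p = 0.0307 with AGS fitted alone and 0.0731 among genes of at least 1 CPM in both lines, where the YAP/TAZ list had 0.000593. PLAU, TIMP3, IGFBP3 and FSTL1 averaged below 1 CPM in AGS and are abundant in MKN1.

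Genes of the p53 response and of apoptosis were lower in treated AGS cells. BAX, a pore-forming mediator of apoptosis and a p53 target, went from 266.2 ± 40.9 CPM to 133.4 ± 6.85 CPM (SE of the log2 fold change 0.15, adjusted p = 0.00104). BTG2, an antiproliferative p53 target, fell by 0.79 (SE 0.13, adjusted p = 0.00171), BAD fell by 0.86 (SE 0.16, adjusted p = 0.00321), and HTRA2, a mitochondrial protease gene, fell by 0.72 (SE 0.14, adjusted p = 0.00405). CFLAR, an inhibitor of caspase 8 activation, rose by 0.67 (SE 0.14, adjusted p = 0.00707). Of 29 p53 target genes, 11 were lower and 2 higher over all genes, and 15 lower and 2 higher over the list alone (median −0.38, adjusted p = 0.000724). The p53 list had adjusted p = 0.235 with an estimated correlation. Of 25 pro-apoptotic genes, 7 were lower over all genes and 11 over the list alone (median −0.32, adjusted p = 0.00219), with adjusted p = 0.371 with an estimated correlation.

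Genes of proliferation, respiration and NRF2 activity also moved down in AGS. CDC20, an activator of the anaphase-promoting complex, fell by 0.94 (SE 0.16, adjusted p = 0.00193), PLK1, a mitotic kinase gene, by 0.78 (SE 0.15, adjusted p = 0.00378), and CDT1, a replication licensing factor gene, by 0.70 (SE 0.12, adjusted p = 0.00257). Of 36 G2/M and mitosis genes, 8 were lower over all genes and 9 over the list alone (median −0.24, adjusted p = 0.0124), with adjusted p = 0.957 with an estimated correlation and 0.256 with fry. Of 35 DNA replication and G1/S genes, 11 were lower and 12 over the list alone (median −0.24, adjusted p = 0.00171), with adjusted p = 0.722 with an estimated correlation and 0.0704 with fry. UQCRC1, a core subunit of respiratory complex III, fell by 0.58 (SE 0.12, adjusted p = 0.00501). Of 34 nuclear oxidative phosphorylation genes, 16 were lower and 1 higher over all genes, and 21 lower and 1 higher over the list alone (median −0.39, adjusted p = 3.05e-05), with adjusted p = 0.571 with an estimated correlation. Among NRF2 targets, OSGIN1 fell by 1.45 (SE 0.24, adjusted p = 0.00182) and TKT, the transketolase gene, by 0.80 (SE 0.12, adjusted p = 0.00141), while ABCC3, an organic anion exporter gene, rose from 50.02 ± 4.7 CPM to 142 ± 23.1 CPM (adjusted p = 0.0087). Of 24 NRF2 target genes, 7 were lower and 1 higher, and 8 lower and 2 higher over the list alone (median −0.41, adjusted p = 0.0124), with adjusted p = 0.571 with an estimated correlation.

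Among genes of the phosphatases that cantharidin inhibits, the PP2A catalytic genes PPP2CA and PPP2CB changed in AGS by 0.04 (adjusted p = 0.851) and 0.02 (adjusted p = 0.925). The scaffold gene PPP2R1A fell by 0.70 (SE 0.16, adjusted p = 0.00957), PPP2R2D, a regulatory subunit gene, fell by 0.51 (SE 0.11, adjusted p = 0.00874), and the PP1 catalytic gene PPP1CA fell by 0.64 (SE 0.14, adjusted p = 0.00827), with 26.9% of its exon bases shared with other genes. PPP1CB changed by 0.24 (adjusted p = 0.0935) and PPP1CC by −0.26 (adjusted p = 0.0844), and both passed with DESeq2 (0.0249 and 0.044) and with AGS fitted alone (0.00668 and 0.00823), PPP1CC also with the GC and length trend removed (0.00861). Of 28 PP2A and related phosphatase genes, 5 were lower under both adjustments (median −0.20, adjusted p = 0.048), with adjusted p = 0.371 with an estimated correlation. This call ended without AGS untreated replicate 1 (adjusted p = 0.0557), AGS untreated replicate 3 (0.0899) or AGS treated replicate 1 (0.0871). It also ended with DESeq2 size factors (0.061), library totals (0.0539), a filter of 5 CPM (0.066) and among genes of at least 1 CPM in both lines (0.0551).

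Among genes with an ordinary symbol, at least 5 CPM in AGS and no overlap between treated and untreated libraries, the largest increase was that of KLF2 (ENSG00000127528, chromosome 19, 16324817 to 16327874), a transcription factor gene of quiescence, from 3.98 ± 0.645 CPM to 25.5 ± 2.4 CPM (log2 fold change 2.68, SE 0.18, adjusted p = 9.77e-06). The next largest among these were ZC3H6 at 2.42 (SE 0.30, adjusted p = 0.000464), the antisense and therefore uncertain CCDC18-AS1 at 2.34 (SE 0.34, adjusted p = 0.00101), the interferon-inducible SLFN5 at 2.28 (SE 0.41, adjusted p = 0.00296) and the calcium channel gene TRPV6 at 2.21 (SE 0.26, adjusted p = 0.0003). TSPOAP1 (ENSG00000005379, chromosome 17, 58301228 to 58328760), which encodes a scaffold of presynaptic calcium channels, fell from 14.6 ± 1.67 CPM to 0.435 ± 0.0767 CPM (log2 fold change −5.05, SE 0.34, adjusted p = 9.77e-06). ZDHHC11, a palmitoyltransferase gene with a near-identical copy, fell by 3.02 (SE 0.19, adjusted p = 9.77e-06), TMEM217 by 2.54 (SE 0.35, adjusted p = 0.0008), and HYAL3, a hyaluronidase family gene, by 2.31 (SE 0.28, adjusted p = 0.00034). SENP3-EIF4A1 fell by 3.32 (SE 0.65, adjusted p = 0.00452), but 88.0% of its exon bases lie in exons of SENP3, EIF4A1 or other genes. The beta-globin gene HBB had 1520 counts over the untreated and 3 over the treated AGS libraries, a ratio of 436 (95% counting interval 149 to 2120), and its adjusted p = 8.9e-05.

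The other 20 lists did not pass in AGS, some with members in both directions. JUND, an AP-1 subunit gene, fell by 1.35 (SE 0.19, adjusted p = 0.000731) while KLF10 rose by 1.16 (SE 0.20, adjusted p = 0.00213), and of 24 immediate early genes 4 were higher and 6 lower (median −0.12, adjusted p = 0.943). Of 31 hypoxia and glycolysis genes 7 were higher, among them HK2, the hexokinase 2 gene, at 0.93 (SE 0.15), and 9 lower, among them the aldolase gene ALDOA at −0.98 (SE 0.17). The median of that list was 0.03, its mean −0.02 and its test downward (adjusted p = 0.905). CXCL1, a neutrophil chemokine gene, rose by 0.75 (SE 0.16), and of 24 NF-kB target genes 6 were higher (median 0.38, adjusted p = 0.0653). That list passed without AGS untreated replicate 3 (adjusted p = 0.0364), without AGS treated replicate 3 (0.0487), with no filter (0.0278) and with the GC and length trend removed (0.00727). Cytosolic ribosomal protein genes had a median of −0.19 (adjusted p = 0.0653) and passed without AGS untreated replicate 2 (0.00689), AGS treated replicate 1 (0.0423), AGS treated replicate 3 (0.0339), MKN1 treated replicate 2 (0.0418) or MKN1 treated replicate 3 (0.0344). This list also passed with ranks (0.0135), no filter (0.0188) and AGS fitted alone (0.0303), but it had adjusted p = 0.829 with the GC and length trend removed. ERK feedback genes had a median of 0.15 (adjusted p = 0.118), with SPRY1 higher by 0.92 (SE 0.16). Squamous epithelial genes had a median of −0.38 against a mean of 0.03 (adjusted p = 0.528), and the fibroblast, endothelial and blood cell marker genes a median of 0.04 against a mean of −0.68, which HBB drove (adjusted p = 0.528).

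Of the remaining lists in AGS, medians were 0.01 for ATF4 and integrated stress response genes (adjusted p = 0.653), 0.05 for homologous recombination and Fanconi genes (0.676), 0.29 for replication-dependent histone genes (0.459), 0.19 for anti-apoptotic genes (0.385) and 0.04 for autophagy and lysosome genes (0.963). They were −0.15 for ribosome biogenesis genes (0.262), −0.12 for mitochondrially encoded genes (0.943), 0.16 for fatty acid synthesis genes (0.653), 0.07 for interferon-stimulated genes (0.528) and −0.15 for Wnt target genes (0.966). Mesenchymal and TGF-beta genes had a median of −0.27 (0.433), with COL1A1 lower by −0.84. Epithelial junction genes stood at 0.01 (0.731), with KRT19 lower by −0.74, and gastric epithelial genes at 0.04 (0.653), with LGALS4 higher by 0.98 and GATA4 lower by −0.98.

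In total, 4214 of 20280 genes passed in AGS by edgeR's quasi-likelihood test, 1867 higher and 2347 lower, and 1519 of them had an absolute log2 fold change of at least 1. Treated and untreated libraries did not overlap for 52.4% of tested genes, where chance gives 10%. The number fell to 2514 without AGS untreated replicate 1, 2051 without AGS untreated replicate 3, and 2483, 2162 and 2465 without AGS treated replicates 1, 2 and 3. Changes in AGS followed transcript GC content and length (Spearman correlations −0.37 and 0.22 over 12004 genes), with median log2 fold changes of 0.19 in the fifth of lowest and −0.27 in the fifth of highest GC. With the GC and length trends removed together 4361 genes passed, 2168 higher and 2193 lower. That fit also centres each library on the mean of its line, so it cannot show whether these trends caused the excess of lower genes. Of the 4214 calls, 3304 were kept with the same sign, HSPB1 not among them (adjusted p = 0.0805).

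**Figure D2:**
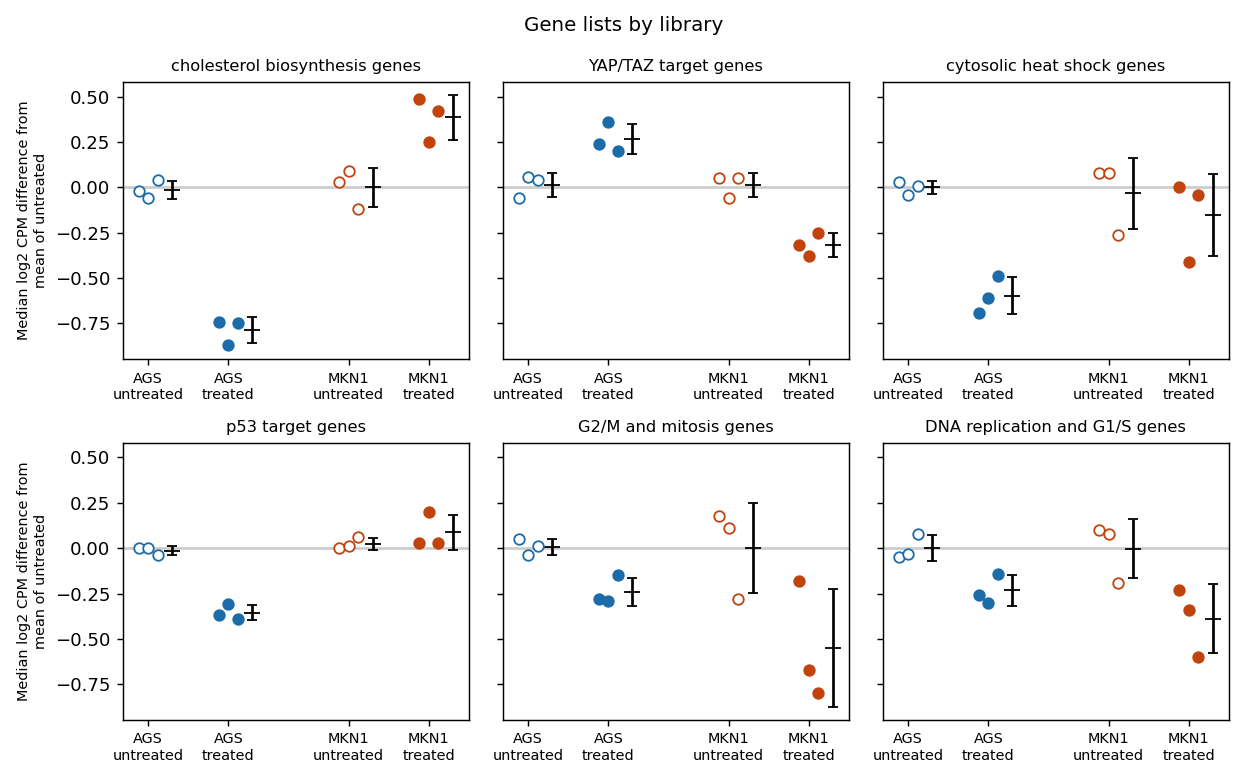
Median log2 CPM difference of 6 gene lists from the mean of the untreated libraries, per library, with mean ± SD of 3 libraries. Cholesterol genes lay at −0.74, −0.87 and −0.75 in treated AGS and at 0.49, 0.25 and 0.42 in treated MKN1 libraries.

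The comparison in MKN1 asked the same question in the other line. Mitosis and replication genes fell in treated MKN1 cells (n = 3 per group throughout). UBE2C (ENSG00000175063, chromosome 20, 45812576 to 45816957), a ubiquitin-conjugating enzyme of mitotic exit, went from 299.6 ± 37.9 CPM to 155.8 ± 22.2 CPM (log2 fold change −0.94, SE 0.13, adjusted p = 0.00314). CCNB1, the cyclin B1 gene, fell by 0.96 (SE 0.15, adjusted p = 0.00557), and PRC1, a gene of the central spindle, by 0.78 (SE 0.14, adjusted p = 0.00791). Of 36 G2/M and mitosis genes, 8 were lower over all genes and 25 over the list alone (median −0.52, adjusted p = 4.5e-15), with adjusted p = 0.525 with an estimated correlation. Library medians of this list were 0.18, 0.11 and −0.28 in untreated and −0.18, −0.67 and −0.80 in treated cells, so untreated replicate 3 lay below treated replicate 1. LIG1, the replicative DNA ligase gene, fell by 0.97 (SE 0.16, adjusted p = 0.0062), and E2F1, a transcription factor of the G1/S transition, by 0.89 (SE 0.15, adjusted p = 0.00697). Of 35 DNA replication and G1/S genes, 7 were lower over all genes and 17 over the list alone (median −0.38, adjusted p = 8.63e-10), with adjusted p = 0.525 with an estimated correlation. FANCA, a gene of the Fanconi core complex, fell by 0.71 (SE 0.12, adjusted p = 0.00577). Of 25 homologous recombination and Fanconi genes, 5 were lower and 1 higher, and 8 lower and 1 higher over the list alone (median −0.21, adjusted p = 0.00694), with adjusted p = 0.635 with an estimated correlation, 0.605 without MKN1 treated replicate 3, and 0.202 with fry. In that list untreated replicate 3 (−0.23) lay below treated replicates 1 (0.05) and 2 (−0.03).

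Cholesterol genes rose in MKN1, against the direction in AGS. SQLE (ENSG00000104549, chromosome 8, 124998497 to 125022283), a rate-limiting monooxygenase of the pathway, went from 37.33 ± 2.2 CPM to 74.13 ± 16.2 CPM (log2 fold change 0.99, SE 0.16, adjusted p = 0.0056). DHCR7 rose by 0.81 (SE 0.13, adjusted p = 0.00596), CYP51A1 by 0.61 (SE 0.10, adjusted p = 0.00656) and FDFT1, the squalene synthase gene, by 0.56 (SE 0.09, adjusted p = 0.00557). Of 25 cholesterol genes, 6 were higher and 0 lower over all genes, and 12 higher and 1 lower over the list alone (median 0.42, adjusted p = 7.08e-07). The list gave adjusted p = 0.525 with an estimated correlation.

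YAP/TAZ targets fell in MKN1, again against AGS. CCN1, a matricellular protein gene, went from 777.6 ± 218 CPM to 312.1 ± 29.4 CPM (log2 fold change −1.32, SE 0.22, adjusted p = 0.00588). ANKRD1 (ENSG00000148677, chromosome 10, 90912096 to 90921276), an ankyrin repeat protein gene, went from 41.0 ± 25.3 CPM to 6.02 ± 0.852 CPM (log2 fold change −2.76, SE 0.47, adjusted p = 0.00707). Of 24 YAP/TAZ target genes, 7 were lower and 0 higher over all genes, and 9 lower and 2 higher over the list alone (median −0.28, adjusted p = 0.00345), with adjusted p = 0.525 with an estimated correlation. CCL2 (ENSG00000108691, chromosome 17, 34255218 to 34257203), a monocyte chemokine gene, fell from 64.0 ± 20.7 CPM to 10.1 ± 4.53 CPM (log2 fold change −2.66, SE 0.37, adjusted p = 0.00268), and TNFAIP2 fell by 1.05 (SE 0.14, adjusted p = 0.00226). Of 24 NF-kB target genes, 3 were lower over all genes, and 5 lower and 2 higher over the list alone (median −0.25, adjusted p = 0.0177). That list had adjusted p = 0.622 with an estimated correlation, 0.291 without MKN1 treated replicate 1, 0.102 with the GC and length trend removed, 0.0965 with ranks, 0.0521 with a filter of 5 CPM, 0.145 with fry and 0.0845 among genes of at least 1 CPM in both lines. Its library medians were −0.03, 0.04 and −0.04 in untreated and −0.35, 0.14 and −0.25 in treated cells, so treated replicate 2 lay above all untreated libraries.

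Stress and death genes rose in part. DDIT3 (ENSG00000175197, chromosome 12, 57516588 to 57521737), the stress transcription factor gene CHOP, went from 17.9 ± 2.17 CPM to 75.2 ± 50.3 CPM (log2 fold change 2.07, SE 0.36, adjusted p = 0.00772), with 39.6% of its exon bases shared with other genes. SESN2, a stress-induced regulator of mTORC1, rose by 1.90 (SE 0.42, adjusted p = 0.022), a call that ended without MKN1 untreated replicate 1 (adjusted p = 0.0738), untreated replicate 2 (0.11), treated replicate 2 (0.0802) or treated replicate 3 (0.0535), and with voom (0.0512). Of 30 ATF4 and integrated stress response genes, 2 were higher and 1 lower, and 4 higher and 1 lower over the list alone (median 0.35, adjusted p = 0.00428). The list had adjusted p = 0.635 with an estimated correlation, and it was lost without MKN1 untreated replicate 1 (0.133), treated replicate 2 (0.241) or treated replicate 3 (0.0767), and with fry (0.333). Untreated replicate 3 (0.61) lay above treated replicates 1 (−0.28) and 3 (0.43) in its library medians. CASP8, the initiator caspase gene of death receptors, rose from 51.83 ± 2.44 CPM to 86.32 ± 13.7 CPM (log2 fold change 0.74, SE 0.12, adjusted p = 0.00508). Of 25 pro-apoptotic genes, 4 were higher and 1 lower, and 8 higher and 1 lower over the list alone (median 0.15, adjusted p = 0.0415), with adjusted p = 0.622 with an estimated correlation. That call was lost without MKN1 untreated replicate 1 (0.244), untreated replicate 2 (0.165), treated replicate 2 (0.0618) or treated replicate 3 (0.102), without AGS untreated replicates 2 (0.0512) or 3 (0.051), and without AGS treated replicate 3 (0.0515). It was also lost with ranks (0.131), fry (0.134) and each line fitted alone (0.0693), and its median in untreated replicate 3 (0.19) lay above those in treated replicates 1 (0.16) and 2 (0.14).

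Some interferon and epithelial genes were lower in MKN1. ISG15, an interferon-induced ubiquitin-like modifier gene, fell by 1.46 (SE 0.29, adjusted p = 0.0145), a call that ended without MKN1 untreated replicate 2 (0.0571). Of 30 interferon-stimulated genes, 4 were lower over all genes and 9 over the list alone (median −0.56, adjusted p = 8.35e-06), with adjusted p = 0.635 with an estimated correlation, 0.0568 without MKN1 treated replicate 3 and 0.202 with fry. Its library medians overlapped between the groups, since untreated replicate 3 (−0.58) lay below treated replicates 1 (−0.15) and 2 (−0.17). CLDN7, a tight junction claudin gene, fell from 10.0 ± 0.89 CPM to 4.69 ± 0.923 CPM (adjusted p = 0.00214). Of 27 epithelial junction genes, 2 were lower under both adjustments (median −0.21, adjusted p = 0.0372), with adjusted p = 0.559 with an estimated correlation, 0.106 without MKN1 untreated replicate 3, 0.337 without MKN1 treated replicate 3, 0.107 with a filter of 5 CPM, 0.0924 with fry and 0.0845 among genes of at least 1 CPM in both lines. MUC1, a membrane mucin gene, fell from 249.9 ± 26.5 CPM to 106.4 ± 19.3 CPM (log2 fold change −1.23, SE 0.16, adjusted p = 0.002), and gastric epithelial genes had a median of −0.06 (adjusted p = 0.702).

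Further lists passed in MKN1 with few single genes. AKR1C3, an aldo-keto reductase gene with close paralogs, fell by 1.85 (SE 0.26, adjusted p = 0.00268), and of 24 NRF2 target genes 5 were lower, and 9 lower and 1 higher over the list alone (median −0.23, adjusted p = 0.00418), with adjusted p = 0.559 with an estimated correlation and 0.0784 with fry. In that list untreated replicate 3 (−0.21) lay below treated replicate 1 (−0.19). Of 34 nuclear oxidative phosphorylation genes, 5 were lower and 10 over the list alone (median −0.30, adjusted p = 7.08e-07), with adjusted p = 0.559 with an estimated correlation. ERK feedback genes had a median of 0.38, with 1 of 18 higher over all genes and 4 over the list alone (adjusted p = 0.0022, and adjusted p = 0.525 with an estimated correlation). By edgeR 0 genes passed, over all genes or over the list alone, among the 33 cytosolic ribosomal protein genes (median −0.21, adjusted p = 0.000191) and the 13 mitochondrially encoded genes (median −0.28, adjusted p = 0.00444). Unadjusted p lay below 0.05 for 6 and 3 of them, DESeq2 called 1 and 0, and voom called 0 in either list. Both had adjusted p = 0.635 with an estimated correlation, and without MKN1 treated replicate 2 their values were 0.0654 and 0.137, and with fry 0.202 for each. Library medians overlapped in both. Ribosomal protein genes had −0.12, 0.15 and −0.02 in untreated and −0.28, −0.47 and 0.01 in treated cells, and mitochondrially encoded genes 0.07, 0.22 and −0.27 against 0.03, −0.61 and −0.35.

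Among genes meeting the same conditions in MKN1, the largest increases after DDIT3 were CMKLR2, a chemerin receptor gene, at 1.95 (SE 0.32, adjusted p = 0.00577), RNF125 at 1.49 and the antisense genes UCKL1-AS1 at 1.66 and ICAM4-AS1 at 1.65, which are uncertain without strand. TMCC3 rose by 1.51. The calls of ICAM4-AS1 and TMCC3 ended without MKN1 untreated replicate 1 (adjusted p = 0.0514 and 0.0521) and treated replicate 2 (0.0768 and 0.0563), and that of TMCC3 also without untreated replicate 2 (0.068). Further decreases were IDO1, a tryptophan-degrading enzyme gene, at −2.51, MT1E, a metallothionein gene with close copies, at −2.10, and MFSD4A at −1.94 (SE 0.27, adjusted p = 0.00248). The call of IDO1 ended without MKN1 untreated replicate 2 (0.0702) and treated replicate 2 (0.052), and with DESeq2 (0.0783). UGT1A6, a glucuronosyltransferase gene, fell by 1.91 (SE 0.20, adjusted p = 0.000605), but 64.4% of its exon bases are shared with other genes of the UGT1A cluster, so the gene remains uncertain.

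The phosphatase genes PPP2CA, PPP2CB, PPP1CA, PPP1CB and PPP1CC changed by 0.01, 0.04, −0.06, −0.01 and 0.20 in MKN1, with adjusted p from 0.255 to 0.981, and the PP2A list had a median of 0.08 (adjusted p = 0.162).

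Of the remaining lists in MKN1, hypoxia and glycolysis genes had a median of 0.10 (adjusted p = 0.087) and passed without MKN1 untreated replicate 2 (0.0332), treated replicate 1 (0.0157) or treated replicate 2 (0.0187), and with library totals (0.0379), no filter (0.0494), a filter of 5 CPM (0.0491) or the GC and length trend removed (0.0403). Within it, PDK1, a kinase that restrains pyruvate oxidation, rose by 0.83 (SE 0.15) and PFKL, the liver phosphofructokinase gene, fell by 0.80 (SE 0.11). Cytosolic heat shock genes had a median of −0.14 (0.0899) and passed without MKN1 untreated replicate 3 (0.0172) or treated replicate 1 (0.00725), and with no filter (0.0494). P53 target genes had a median of 0.03 (0.12) and passed upward without MKN1 treated replicate 1 (0.0077), and squamous epithelial genes one of −0.22 (0.262), passing without MKN1 untreated replicate 3 (0.00742). Medians were 0.16 for immediate early genes (0.739), 0.06 for endoplasmic reticulum chaperone genes (0.503), 0.02 for histone genes (0.94), −0.07 for anti-apoptotic genes (0.553), −0.05 for autophagy and lysosome genes (0.333), 0.04 for ribosome biogenesis genes (0.702) and −0.54 for fibroblast, endothelial and blood cell marker genes (0.655). Median and mean differed in sign for fatty acid synthesis genes (−0.05 and 0.01, adjusted p = 0.739), Wnt target genes (0.18 and −0.06, 0.845), mesenchymal and TGF-beta genes (0.03 and −0.05, 0.845) and matrix protease and invasion genes (0.07 and −0.02, 0.94).

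In total, 1358 genes passed in MKN1, 567 higher and 791 lower, and 458 had an absolute log2 fold change of at least 1. With library totals 754 were higher and 543 lower, and with the GC and length trend removed 990 and 889, so which direction prevails depends on these choices. Treated and untreated libraries did not overlap for 21.4% of genes, where chance gives 10%. The joint fit estimates its spread over both lines, and replicates varied more in MKN1 than in AGS. Its p-values for MKN1 therefore do not measure the spread of MKN1 alone. With MKN1 fitted alone by edgeR only 34 genes passed, and 40 of the 45 named calls in MKN1 were lost. The number was 336 without MKN1 untreated replicate 2, 3160 without untreated replicate 3, 756 without untreated replicate 1 and 624 without treated replicate 2, and 879, 838, 892 and 832 without AGS untreated replicates 1 and 2 and AGS treated replicates 1 and 3.

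The last comparison asked where the response to treatment differs between the lines, as MKN1 minus AGS. The cholesterol list differed most, with DHCR7 at 2.44 (SE 0.19, adjusted p = 2.38e-05), SQLE at 1.98 (SE 0.22, adjusted p = 0.000265), ACAT2 at 1.79 (SE 0.19, adjusted p = 0.00021) and FASN, outside the list, at 1.75 (SE 0.20, adjusted p = 0.000294). Of 25 cholesterol genes, 18 had a positive and 0 a negative difference, and 20 were positive over the list alone (median 1.17, adjusted p = 9.98e-23), with adjusted p = 0.0665 with an estimated correlation. YAP/TAZ targets differed the other way, with ANKRD1 at −4.50 (SE 0.64, adjusted p = 0.000985), CCN2 at −2.98 (SE 0.61, adjusted p = 0.00623) and CCN1 at −1.83 (SE 0.31, adjusted p = 0.0023). Of 24 genes, 12 had a negative difference under both adjustments (median −0.39, adjusted p = 7.35e-07), with adjusted p = 0.0665 with an estimated correlation. Among genes of at least 1 CPM in both lines this list kept adjusted p = 5.18e-05.

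**Figure D3:**
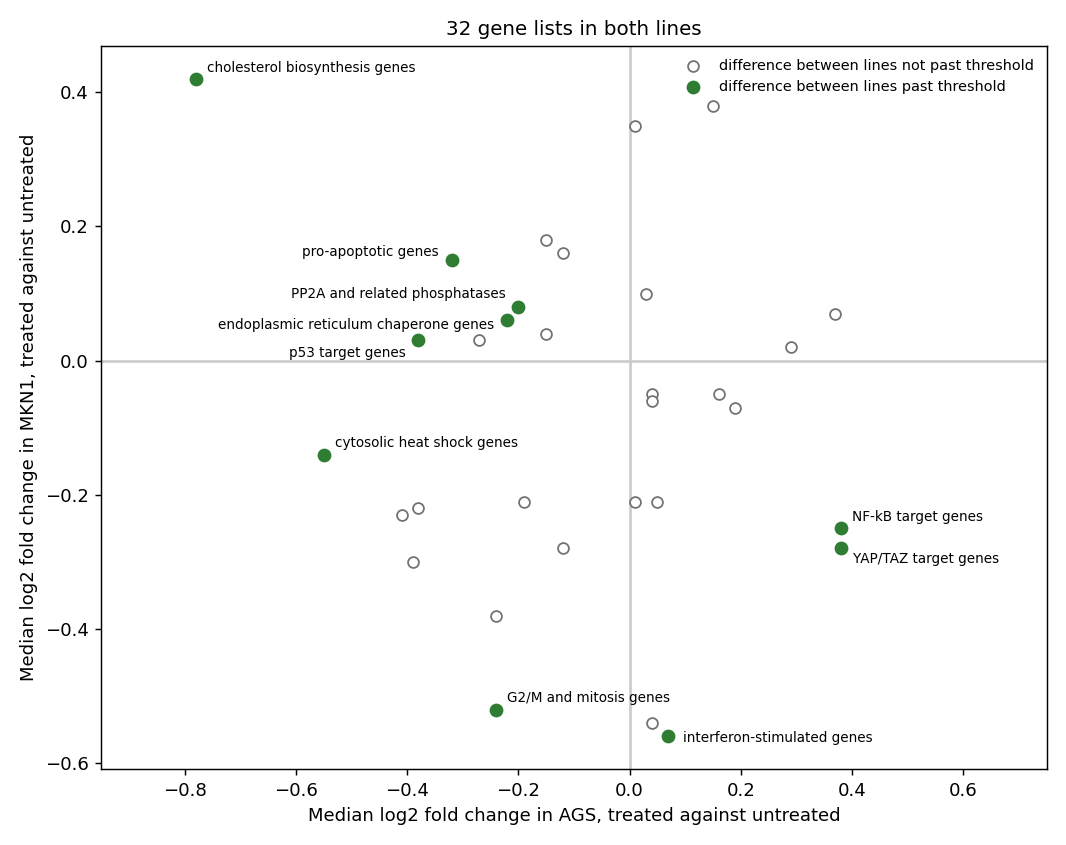
Median log2 fold changes of 32 gene lists in AGS and MKN1. The difference between the lines passed for 10 lists, 0 of them with an estimated correlation (lowest adjusted p = 0.0665), among them cholesterol biosynthesis genes (−0.78 in AGS, 0.42 in MKN1) and YAP/TAZ target genes (0.38 and −0.28).

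P53 targets, apoptosis genes and chaperone genes had more positive log2 fold changes in MKN1 than in AGS. In MKN1 itself the p53, endoplasmic reticulum chaperone and cytosolic heat shock lists did not pass (medians 0.03, 0.06 and −0.14). BTG2 differed by 1.36 (SE 0.18, adjusted p = 0.00076), BIK, a BH3-only gene, by 1.81 (SE 0.33, adjusted p = 0.00374) and CASP8 by 0.71 (SE 0.16, adjusted p = 0.0108). Of 29 p53 targets, 9 were positive and 1 negative, and 14 and 2 over the list alone (median 0.65, adjusted p = 0.000628), with adjusted p = 0.231 with an estimated correlation. Of 25 pro-apoptotic genes, 6 were positive and 8 over the list alone (median 0.57, adjusted p = 0.000628), with adjusted p = 0.339 with an estimated correlation. CALR differed by 1.13 (SE 0.19, adjusted p = 0.00251), and of 22 endoplasmic reticulum chaperone genes 9 were positive and 1 negative, and 10 and 1 over the list alone (median 0.34, adjusted p = 0.00179), with adjusted p = 0.522 with an estimated correlation. FKBP4 differed by 1.15 (SE 0.20, adjusted p = 0.00297), and 3 of 19 cytosolic heat shock genes were positive under both adjustments (median 0.40, adjusted p = 0.0274), with adjusted p = 0.819 with an estimated correlation. This heat shock call ended without AGS treated replicate 1 (0.0756), MKN1 untreated replicate 3 (0.12) or MKN1 treated replicate 1 (0.104), and with fry (0.127).

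Inflammatory genes had lower responses in MKN1. TNFAIP2 differed by −1.39 (SE 0.20, adjusted p = 0.000924), and of 24 NF-kB target genes 7 were negative under both adjustments (median −0.61, adjusted p = 0.00698), with adjusted p = 0.571 with an estimated correlation and 0.0592 with fry. STAT2, a transducer of interferon signals, differed by −1.12 (SE 0.18, adjusted p = 0.00207), and 4 of 30 interferon-stimulated genes were negative under both adjustments (median −0.61, adjusted p = 0.00179), with adjusted p = 0.905 with an estimated correlation and 0.328 with fry. PPP2R2D differed by 0.70 (SE 0.16, adjusted p = 0.0118), and 4 of 28 PP2A and related phosphatases were positive under both adjustments (median 0.29, adjusted p = 0.0218), with adjusted p = 0.362 with an estimated correlation. Of 36 G2/M and mitosis genes, 1 was negative under both adjustments (HMMR, named after its value was seen, at −1.07), with a median of −0.33 (adjusted p = 0.0195), and adjusted p = 0.905 with an estimated correlation. This call ended without MKN1 untreated replicate 1 (0.0963), treated replicate 2 (0.111) or treated replicate 3 (0.0975), with fry (0.412), and among genes of at least 1 CPM in both lines (0.0506).

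**Figure D4:**
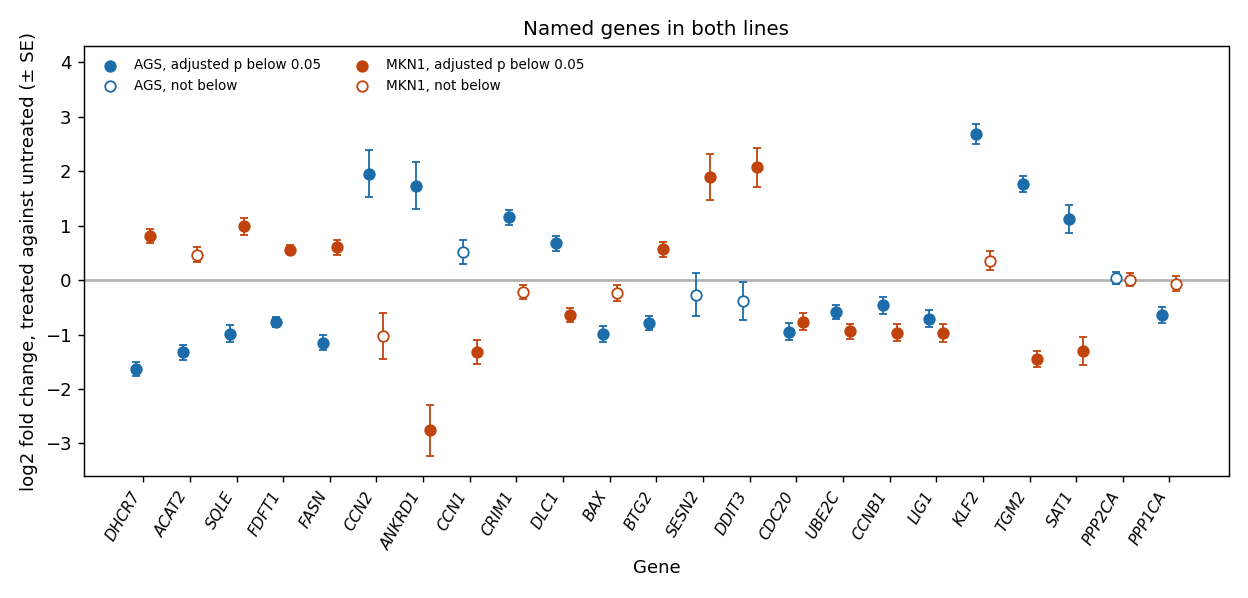
Log2 fold changes ± SE of 23 genes in both lines, filled where the adjusted p was below 0.05. DHCR7 stood at −1.64 in AGS and 0.81 in MKN1, TGM2 at 1.76 and −1.45.

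Among genes expressed at 5 CPM or more in both lines and separated in opposite directions, a choice made after the values were seen, the largest differences were HYAL3 at 3.68 (SE 0.38, adjusted p = 0.000184), ZDHHC11 at 3.65 (SE 0.25, adjusted p = 1.64e-05) and the antisense FBXL19-AS1 at 2.91. In the other direction, ANKRD1 was followed by TGM2 (ENSG00000198959, chromosome 20, 38127387 to 38166578), the transglutaminase 2 gene, which rose from 31.56 ± 4.76 CPM to 107 ± 1.24 CPM in AGS and fell from 98.07 ± 15.7 CPM to 35.82 ± 5.1 CPM in MKN1 (difference −3.21, SE 0.21, adjusted p = 1.64e-05). SAT1, a polyamine-catabolic enzyme gene, changed by 1.12 in AGS and −1.30 in MKN1, CACNG6 differed by −2.68 and ACSF2 by −2.40.

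By the fixed rule, the largest differences were TSPOAP1 at 6.39 (SE 0.45, adjusted p = 1.64e-05) and 9 genes near the floor in AGS, whose fitted differences depend on the prior count. RFLNB, BOC, ULK2 and PCLO had 177, 55, 28 and 40 counts over the untreated AGS libraries and 0 over the treated ones, at least 50.8-, 15.8-, 8.03- and 11.5-fold lower against a floor of 3 counts over the group. FRG1BP, a pseudogene, PNMA5, QKI, KCTD12 and RASSF8 had 0 counts over the untreated and 18, 21, 20, 12 and 13 over the treated AGS libraries, at least 6.97-, 8.13-, 7.75-, 4.65- and 5.03-fold higher. PNMA5, QKI and RASSF8 are abundant in MKN1, and 18 genes above 300 CPM in MKN1 and below 0.5 CPM in AGS summed to 0.0137% to 0.0208% of their MKN1 level in untreated and 0.0292% to 0.0367% in treated AGS libraries. The call of RASSF8 ended without AGS untreated replicates 1 (adjusted p = 0.0748), 2 (0.0552) or 3 (0.0626) and AGS treated replicates 2 (0.0763) or 3 (0.0515).

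For the difference, 3180 genes passed, 1700 positive and 1480 negative, and 2012 had an absolute log2 difference of at least 1. The number was 2098 without AGS untreated replicate 1. The matrix protease and invasion list missed the threshold (median −0.25, adjusted p = 0.0501), as did homologous recombination and Fanconi genes (median −0.27, adjusted p = 0.0575), DNA replication and G1/S genes (−0.05, 0.332), nuclear oxidative phosphorylation genes (0.11, 0.859), ATF4 and integrated stress response genes (0.21, 0.303) and NRF2 targets (median 0.13, mean −0.12, adjusted p = 0.936). The other 16 lists had adjusted p between 0.175 and 0.936.

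Some of these differences passed elsewhere. The matrix list passed without AGS untreated replicate 2 (0.0345), AGS treated replicates 1 (0.0193) or 3 (0.0262), MKN1 untreated replicate 3 (0.00991) or MKN1 treated replicate 2 (0.0328), and with library totals (0.0467), no filter (0.0187), a filter of 5 CPM (0.0435) or the trend removed (0.0215). The homologous recombination list passed without AGS treated replicate 2 (0.0342), MKN1 untreated replicate 3 (0.0186) or MKN1 treated replicates 1 (0.00775) or 2 (0.0241), and with no filter (0.012) or ranks (0.0494). ATF4 genes passed without MKN1 untreated replicate 3 (0.0143) or treated replicate 1 (0.00054), and mitochondrially encoded genes without the same libraries (0.0325 and 0.00797). Cytosolic ribosomal protein genes passed without MKN1 treated replicate 3 (0.028), and anti-apoptotic genes with fry (0.0311).

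Genes called in both lines were more often opposite than alike. LIG1 fell in both lines (−0.71 in AGS and −0.97 in MKN1), as did UBE2C (−0.58 and −0.94) and HSPB1 (−0.77 and −0.86), and PDK1 rose in both (0.76 and 0.83). In all, 42 genes rose in both lines and 79 fell in both, where independent lists would share 52.2 and 91.5. In opposite directions, 163 genes rose in AGS and fell in MKN1 and 139 the reverse, where independent lists would share 72.8 and 65.6. The 302 opposite genes exceeded the 138.4 expected, as they did in every setting and with each library left out. The 121 alike fell short of the 143.7 expected, but without MKN1 treated replicate 3 there were 215 against 154.1, without MKN1 untreated replicate 3 there were 435 against 418.0, and with no filter 52 against 43.3. Without MKN1 untreated replicates 1 or 2 or treated replicate 2 there were 62, 12 and 35 alike and 181, 104 and 204 opposite, and without MKN1 untreated replicate 3 there were 633 opposite. Without each AGS library in turn there were 39 to 53 alike and 134 to 145 opposite. The lines share no libraries but share the spread estimate of the joint fit, so their calls are not fully independent. With each line fitted alone, 11 genes were opposite (5.4 expected) and 1 alike (5.6 expected). The log2 fold changes of 10260 genes of at least 5 CPM in both lines had a Pearson correlation of −0.16 and a Spearman correlation of 0.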

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

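The tests of the cholesterol and YAP/TAZ pattern, of the comparison of globin levels with other libraries, of MKN1 untreated replicate 3 and of other sample splits for single lists were chosen only after the result was seen. The results below were singled out because the response to treatment differed between AGS and MKN1 in a direct test of that difference. Values are log2 differences, MKN1 minus AGS, with adjusted p below 0.05 in edgeR.

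In all, 3180 genes differed. Of the lists, cholesterol biosynthesis genes differed by a median of 1.17, YAP/TAZ target genes by −0.39, p53 target genes by 0.65, pro-apoptotic genes by 0.57, endoplasmic reticulum chaperone genes by 0.34, cytosolic heat shock genes by 0.40, PP2A and related phosphatases by 0.29, interferon-stimulated genes by −0.61, NF-kB target genes by −0.61 and G2/M and mitosis genes by −0.33. None of the 10 passed with an estimated correlation, where the lowest adjusted p was 0.0665. The G2/M list was lost without MKN1 untreated replicate 1 (0.0963), treated replicate 2 (0.111) or treated replicate 3 (0.0975). The heat shock list was lost without AGS treated replicate 1 (0.0756), MKN1 untreated replicate 3 (0.12) or MKN1 treated replicate 1 (0.104).

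Among lipid genes, DHCR7 differed by 2.44, SQLE by 1.98, ACAT2 by 1.79, FASN by 1.75 and FDFT1 by 1.34. Among YAP/TAZ targets, ANKRD1 differed by −4.50, CCN2 by −2.98, CCN1 by −1.83, CRIM1 by −1.37 and DLC1 by −1.31. P53 and death genes differed by 2.16 (SESN2), 1.81 (BIK), 1.36 (BTG2), 0.76 (BAX), 0.71 (CASP8) and −0.90 (CFLAR). Chaperone and NRF2 genes differed by 1.11 (MANF), 1.13 (CALR), 1.15 (FKBP4), 2.10 (OSGIN1), 1.07 (TKT), −1.38 (AKR1C3) and −0.59 (FTH1). Inflammatory genes differed by −0.68 (CXCL1), −1.39 (TNFAIP2), −1.12 (STAT2), −1.34 (ISG15) and −1.66 (CD68). CD68, XRCC3 and FTH1 are uncertain, because 85.8%, 76.7% and 62.4% of their exon bases lie in exons of other genes.

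Replication and repair genes differed by −0.82 (E2F1), −1.01 (FANCA), −1.08 (EME1) and −0.64 (XRCC3), and phosphatase genes by 0.70 (PPP2R2D) and 0.46 (PPP1CC). Metabolic and autophagy genes differed by −1.16 (PFKL) and 1.30 (TP53INP2). Epithelial and surface genes differed by 1.11 (KRT19), −1.23 (LGALS4), 1.02 (TRIM29), −1.23 (ITGA3), −1.18 (CLDN7), −1.88 (MUC1) and 0.74 (TNFRSF19).

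Of the genes that changed most in AGS, KLF2 differed by −2.32, ZC3H6 by −2.53, CCDC18-AS1 by −2.92, SLFN5 by −2.25, TRPV6 by −1.96, TSPOAP1 by 6.39, ZDHHC11 by 3.65, TMEM217 by 3.88 and HYAL3 by 3.68. Of those that changed most in MKN1, DDIT3 differed by 2.45, CMKLR2 by 2.12, UCKL1-AS1 by 2.21, ICAM4-AS1 by 3.46, TMCC3 by 1.86, MFSD4A by −2.62 and UGT1A6 by −1.98. Genes chosen after their values were seen differed by 2.91 (FBXL19-AS1), −3.21 (TGM2), −2.68 (CACNG6), −2.42 (SAT1) and −2.40 (ACSF2). Fitted differences of genes near the floor in AGS were 7.16 (HBB), 8.78 (RFLNB), 7.56 (BOC), 6.40 (ULK2), 6.22 (PCLO), −5.77 (FRG1BP), −5.64 (PNMA5), −5.56 (QKI), −4.80 (KCTD12) and −4.65 (RASSF8), and none of these is a bound on the true fold.

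With 1 library left out, 61 of these 74 gene differences always passed and 13 were lost at least once, 3 to 11 of them for each library. The highest adjusted p came without AGS treated replicate 1 for TRIM29 (0.0618), TMCC3 (0.0726) and PPP1CC (0.121), without AGS treated replicate 2 for RASSF8 (0.0763), and without AGS treated replicate 3 for AKR1C3 (0.0691) and CXCL1 (0.127). It came without AGS untreated replicate 1 for E2F1 (0.0606), FTH1 (0.0727) and ISG15 (0.101), without AGS untreated replicate 2 for XRCC3 (0.117), without AGS untreated replicate 3 for BAX (0.0713), and without MKN1 untreated replicate 2 for SESN2 (0.0657) and LGALS4 (0.104).

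The cholesterol list had a negative median in AGS and a positive one in MKN1, and the YAP/TAZ list the reverse, although in MKN1 only 6 of 25 and 7 of 24 genes passed. With an estimated correlation neither list passed, at adjusted p = 0.147 in AGS, 0.525 in MKN1 and 0.0665 for the difference in each. A bias of GC content or gene length as the whole cause is argued against, because the larger adjusted p of the 2 differences was 8.09e-07 with that trend removed. Without MKN1 untreated replicate 3 the larger value was 1.95e-08, although a change in AGS alone could give such a difference. In MKN1 itself, leaving this library out moved the cholesterol median from 0.42 to 0.27 (camera adjusted p = 0.00288). The YAP/TAZ median moved from −0.28 to −0.22 (camera adjusted p = 0.0018). Both lists therefore kept their direction in MKN1 without this library, with smaller medians. All 6 pairs of medians under 3 other scalings kept opposite signs. These scalings could hardly have turned a sign, because they gave a median of all genes in MKN1 of at most 0.081. Unequal dose, exposure or growth state of the lines, which the labels do not give, stays open, and no biological explanation was tested.

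Globin transcripts were present in untreated AGS libraries and almost absent from treated ones, and both MKN1 groups held them too. HBA1 averaged 1.49 CPM in untreated AGS, 0.989 CPM in untreated MKN1 and 1.31 CPM in treated MKN1 libraries. The mean of HBB in treated MKN1 libraries was 1.67 CPM. HBB had 958, 297 and 265 counts in the untreated and 0, 3 and 0 in the treated AGS libraries, and HBA1 and HBA2, near-identical copies of each other, were at least 56.2- and 72.3-fold lower against a floor of 3 counts over the group. Reads from other libraries of the series are argued against as the source, because the highest mean HBB level elsewhere, in untreated MKN1 cells, was 3.97 CPM against 11.2 ± 6.42 CPM in untreated AGS cells. Blood RNA in the untreated AGS libraries cannot be told apart from globin expression by the cells. Of detected white cell markers, 46.7% (7 of 15) were higher in every untreated library and 0 in every treated library. Among the 7 were CORO1A with 178 against 66 counts and CD37 with 312 against 120, while PTPN6 held 3471 against 3097. This share is weak evidence, because treated and untreated AGS libraries did not overlap, in either direction, for 52.4% of all tested genes. The share of all genes higher in every untreated library was not counted. Low globin expression that ends with treatment could also give the globin pattern in AGS, and no biological explanation was tested.

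MKN1 untreated replicate 3 stood apart from untreated replicates 1 and 2. On the axis from the untreated (0) to the treated (1) mean of the other MKN1 libraries it lay at 0.70, above the lowest treated library left out in the same way (0.64), while untreated replicates 1 and 2 lay at 0.22 and 0.17. A bias of GC content or gene length is argued against, as the SD of its log2 differences from replicates 1 and 2 stayed at 0.568 with that trend removed, against 0.299 between those replicates. A treated sample with an untreated label cannot be told apart from an untreated sample in another state. That position speaks for the former, while the SD of its differences from treated libraries (0.549, 0.602 and 0.535) lay above that between treated libraries (0.432, 0.497 and 0.517). From untreated replicates 1 and 2 the SD was 0.62 and 0.58. With the trend removed, the SD from treated libraries (0.502, 0.555 and 0.534) lay below that from these replicates (0.576 and 0.561). Its medians for the cholesterol (−0.12) and YAP/TAZ (0.05) lists also lay nearer those of untreated replicates 1 and 2 (0.03 and 0.09, 0.05 and −0.06) than those of treated cells (0.25 to 0.49, and −0.38 to −0.25), while its G2/M median (−0.28) lay below that of treated replicate 1 (−0.18). Its medians for ATF4 (0.61), interferon-stimulated (−0.58), homologous recombination (−0.23), NRF2 (−0.21), pro-apoptotic (0.19) and mitochondrially encoded genes (−0.27) also lay beyond treated replicate 1. Those of ERK feedback (−0.31), NF-kB (−0.04), DNA replication (−0.19), oxidative phosphorylation (−0.04), ribosomal protein (−0.02) and epithelial junction genes (0.10) did not. All results keep the label as deposited, and no biological explanation was tested.

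Other splits of the libraries show how far chance groupings reach. Within a line the 10 splits are too few to exclude chance. In AGS the real split gave 4214 genes, reached by 1 of the 10, and the highest other 1, and it gave 12 lists, reached by 2 of the 10, with a highest other of 12. In MKN1 the real split gave 1358 genes, reached by 1 of the 10, and the highest other 441, and it gave 15 lists, reached by 3 of the 10, with a highest other of 17. For the difference, 100 of 200 possible splits were drawn. The 3180 genes were reached by 1 of the 100, the real split itself (highest other 2642). A split run only within MKN1, with AGS as labelled and MKN1 untreated replicates 2 and 3 grouped with treated replicate 3, gave 3116 while calling 0 genes in MKN1. Other splits with AGS as labelled gave 106 to 2642, so a number near 3180 also arises with mixed MKN1 groups. The 10 lists were reached by 67 of the 100 (highest other 18), so the number of lists is not beyond chance.

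The 302 genes called in opposite directions were reached by 1 of the 100 splits (highest other 121). The 121 genes called in the same direction were reached by 2 of the 100, where the other split mirrors the labels of 1 line and gives 302. Neither comparison can exclude chance. Splits that mix the AGS groups called at most 1 gene in AGS, so almost no gene could be called in both lines. The difference of the cholesterol list had an unadjusted camera p as small in 1 of the 100 splits, the real one itself. Its adjusted p was 9.98e-23 for the real split and 1.33e-21 for the lowest other. It passed the threshold in 55 of the 100. Within AGS the list passed in 10 of 10 splits (adjusted p = 1.12e-18 for the real, 1.22e-06 for the lowest other). Within MKN1 it passed in 4 of 10, where 3 had an unadjusted p as small (adjusted p = 7.08e-07 and 1.29e-12). The YAP/TAZ difference had an unadjusted p as small in 2 of the 100 and passed in 37. Its adjusted p was 7.35e-07 for the real split and 2.55e-07 for the lowest other. The other 8 called differences were matched in 5% of the splits or more, so chance is not excluded for them. PP2A and related phosphatases were matched by 6 of the 100, pro-apoptotic genes by 7, endoplasmic reticulum chaperone genes by 7 and p53 target genes by 9. NF-kB target genes were matched by 15, heat shock genes by 41, interferon-stimulated genes by 44 and G2/M genes by 57. Nor do the counts of 1 and 2 exclude chance for the cholesterol and YAP/TAZ differences. Splits that mix the AGS groups lose the AGS effect, and these lists were singled out after the values were seen.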

How the results depend on the processing

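The restrictions to genes of at least 1 CPM, the list test on each line alone and the fit with GC and length trend removed were chosen only after the data had been seen. No called result reversed its direction under a setting that was run. In AGS, 4214 genes passed, and 8368 with each line fitted alone. Leaving out 1 library gave 2051 (AGS untreated replicate 3) to 5533 (MKN1 untreated replicate 3). With an absolute log2 fold change of at least 1, 579 passed a filter of 5 CPM, 731 passed among genes of at least 1 CPM and 140 with glmTreat, against 1519. In MKN1, 1358 genes passed, 2459 with DESeq2, 809 with no filter and 34 with the line alone, and leaving out 1 library gave 336 (untreated replicate 2) to 3160 (untreated replicate 3). Of the 458 with the larger fold change, 217 passed at 5 CPM, 34 with the line alone and 3 with glmTreat, and leaving out 1 library gave 168 to 998. For the difference, leaving out 1 library gave 2098 (AGS untreated replicate 1) to 4643 (MKN1 untreated replicate 3), and the 2012 with the larger fold change became 1132 at 5 CPM, 1243 at 1 CPM and 289 with glmTreat.

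Genes shared in the same direction, 121 at first, numbered 288 with DESeq2, 52 with no filter, 1 with each line fitted alone and 5 at an adjusted p below 0.01, and 12 to 435 when 1 library was left out. Genes shared in opposite directions, 302 at first, numbered 543, 164, 11 and 43 in the same order, 509 with the GC and length trend removed, and 104 to 633 when 1 library was left out. With an estimated correlation 0 lists passed camera in AGS, 0 in MKN1 and 0 for the difference, where unadjusted p lay below 0.05 for 3, 2 and 4 lists, and fry called 11, 6 and 7.

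Library totals moved the median of all genes by 0.081 in MKN1 and turned its calls from 41.8% to 58.1% higher, and the fit with GC and length trend removed gave 52.7% higher, so the balance of directions in MKN1 depends on scaling. The cholesterol and YAP/TAZ medians kept their signs with library totals. Same-numbered libraries showed no regular shared deviation (correlations of 0, 0.09 and −0.06 in AGS and 0.16, −0.10 and 0.26 in MKN1). Not every sample correlated best with its own number, but the 0.26 of replicate 3 was the highest value in MKN1. Other-numbered MKN1 pairs ranged from −0.3 to 0.2. With 3 libraries per group this check cannot exclude paired samples. The replicate block gave 4087 genes in AGS, 1207 in MKN1 and 3235 for the difference. It kept 3552 of the 4214 calls in AGS, 894 of the 1358 in MKN1 and 2680 of the 3180 for the difference. With the block the matrix protease (0.0291) and homologous recombination (0.0137) lists passed for the difference, the pro-apoptotic list was lost in MKN1 (0.0538), and of the named genes RASSF8 for the difference (0.0665) and BIK (0.0559), FASN (0.0571) and FTH1 (0.0583) in MKN1 were lost too.

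Of the 50 named calls in AGS, 43 held in every setting that tested them, other than the line alone. A filter of 5 CPM left 49 of the 50 to test. H2AC6, EME1, STAT2, ITGB1, BOP1 and RPS15 were each lost without at least 1 library, and HSPB1 (0.0805), BOP1 (0.19) and RPS15 (0.07) with the trend removed. Of the 45 in MKN1, 25 held in those settings and 5 with the line alone. Without MKN1 untreated replicate 2, 19 of the 45 were lost, among them SESN2 (0.11), and 13 without treated replicate 2. Of the 20 for the difference, 19 held in every setting that tested them. The restriction to genes of at least 1 CPM left only 11 of the 20 to test. RASSF8 was lost with voom (0.0902), with the block and without single AGS libraries. List calls with 1 library left out were alike in 374 fits for AGS, 360 for MKN1 and 364 for the difference, weaker in 3, 17 and 6, and stronger in 7, 7 and 14.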

Other observations

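Families outside the fixed lists were chosen only after the result was seen, while the test of the p53 list was fixed before. These families were counted and not tested as groups. Of 42 proteasome subunit genes of at least 1 CPM, 20 were lower and 1 higher in AGS (median −0.32), where 12.7% of all such genes were lower. In MKN1, 2 were lower and 0 higher, and for the difference 8 were positive and 2 negative. Vacuolar ATPase genes, which acidify lysosomes, had 9 of 21 lower in AGS (median −0.28) and 0 in MKN1, and RNA polymerase II subunit genes had 8 of 17 lower and 1 higher in AGS (median −0.35). With the GC and length trend removed these numbers of lower genes in AGS were 20, 8 and 7. NEAT1, the RNA scaffold of paraspeckles, rose by 1.95 in AGS (SE 0.22, adjusted p = 0.000235), and of 21 host genes of small nucleolar RNAs 7 were higher and 1 lower there (median 0.20).

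Of 4 metallothionein genes, whose products bind zinc and copper, 4 were lower in MKN1 (median −1.62), or 3 with the trend removed, where 4.91% of all genes of at least 1 CPM were lower. In AGS 1 was lower (median −0.78), and the difference between the lines passed for 1 (median −0.84). Among those lower in MKN1 were MT1X at −1.86 (SE 0.31, adjusted p = 0.00598) and MT2A at −1.39 (SE 0.26, adjusted p = 0.01). Their copies share much sequence, so single members are uncertain.

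The log2 fold changes of the p53 target list were more positive in MKN1 (median difference 0.65, adjusted p = 0.000628, and adjusted p = 0.231 with an estimated correlation). The list fell in AGS (median −0.38), where its members BAX and BTG2 were lower, and did not pass in MKN1 (median 0.03, camera adjusted p = 0.12).

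Transcripts abundant in MKN1 rose slightly in treated AGS libraries, from at most 0.0208% to at least 0.0292% of the MKN1 level over 18 genes. Carryover of reads between libraries or a small share of MKN1 cells could give such traces, and neither was tested.

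In MKN1, stress and interferon lists varied between replicates as much as between groups. ATF4 and integrated stress response genes had library medians of −0.32, −0.27 and 0.61 in untreated and −0.28, 0.87 and 0.43 in treated cells. Interferon-stimulated genes had 0.24, 0.28 and −0.58 in untreated and −0.15, −0.17 and −1.14 in treated cells.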
